A study of Mus musculus with 12 samples.

How the data were processed

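Gene expression was measured in the striatum of 12 C57Bl/6 mice, 1 array per mouse. Per the labels, 6 mice carried the TIF-IA mutation made with D1R-Cre and 6 were controls, and 3 mice of each genotype were taken at 9 weeks and 3 at 13 weeks of age. The series text speaks of 5 arrays per condition in 1 place and of 3 mice per group in another, and the 12 arrays deposited, 3 per group, were the ones analysed. The number of arrays limits the precision.

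Per the labels, the authors extracted total RNA, hybridised it to Affymetrix arrays and processed the signals with GCRMA, and the deposited values are on a log2 scale. The version of GCRMA is not given. The deposited table holds 22690 probe sets, with values from 1.09 to 15.48 and array medians from 5.29 to 5.52. After 64 array control probe sets were left out, GEO's platform annotation gave 1 gene symbol for 20380 probe sets, several for 691 and none for 1555. Probe sets with several symbols or none were left out. Updating through the RefSeq table changed 0 symbols.

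The values were used as deposited, without further normalization. Each gene was represented by the probe set with the highest mean over the 12 arrays. Genes were kept when they lay above their array's 40th percentile of all probe sets, 3.51 to 3.81, in at least 3 arrays. This kept 8253 of 12393 genes and removed 4140. Among the genes named for the comparison at 9 weeks, 57 passed the test and 24 of these had other probe sets over the filter. In 2 of them, Nip7 and Bcl2l1, another probe set differed the opposite way by at least 0.5 log2. At 13 weeks this held for 1 gene, Taf1d, of 48 such genes. This count leaves out other probe sets that differed little. At 9 weeks the least agreeing one differed by 0.12 for Ece2, 0.08 for Rps15, -0.12 for Gabarapl1 and 0.05 for Xiap. At 13 weeks it differed by 0.26 for Hspb8 and -0.04 for Cspg4.

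All arrays were fitted together in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), with 1 coefficient for each of the 4 groups and 8 residual degrees of freedom. Mutants were compared with controls at each age and over both ages, the difference of the genotype effects between ages was tested as an interaction, and age was compared within each genotype. P-values were two-sided and adjusted by the Benjamini-Hochberg method, and genes passed at an adjusted p under 0.05. An effect is given as the difference of group means on the log2 scale with its standard error (SE) from limma, and a fold is 2 to the power of that difference. The comparisons at 9 and at 13 weeks share no arrays, so the overlap of their gene lists is set beside the number that independent lists of these sizes would give.

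Of 34 gene lists, 28 had at least 5 measured members and were tested as sets with limma's camera, with its preset correlation of 0.01 between genes and adjustment over the 28 lists within a comparison. The test was repeated with a correlation estimated from the data. For each list, the number of members past the test is given over all genes and adjusted over the list alone. Some lists share members, such as Gfap among the astrocyte and the reactive astrocyte genes. The deleted gene, a fixed panel of markers, the 12 largest rises and falls that passed in each genotype comparison, the 5 largest each way for age in controls, and up to 4 members of each list described with the smallest p were the genes to be named. Lists, naming rule, tests and most alternatives were chosen before the data were examined.

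The alternatives were quantile normalization, median centring, other filters, the mean of a gene's probe sets, every probe set on its own, array weights, a trended and robust prior, an unmoderated test, a fit to the compared groups alone, other thresholds, fry and an estimated correlation for the lists, the replicate number as a block, and each array left out in turn. The labels do not give the sex of the mice, which was read from Xist and Eif2s3y. A term for sex, fits to 1 sex and the removal of genes on X and Y were added after the data had been seen. Other splits of the arrays into groups of the same size were tried, all 10 for 3 against 3 and 100 drawn at random for the interaction and for both ages.

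The procedure was tested on simulated data for all 8253 genes. These used the mean of the controls at 9 weeks for every array and 1 pooled spread per gene, with known changes added. The noise was independent between genes and arrays, so an array that stands apart and correlated genes were not represented. For the comparison at 9 weeks the procedure recovered 68% of genes changed by 1 log2 and 99% of genes changed by 2 log2, with 4% false calls. For 13 weeks these values were 65%, 98% and 4.1%, for the interaction 27%, 85% and 5.1%, for both ages 89%, 100% and 4.5%, for age in controls 56%, 99% and 2.5%, and for age in mutants 63%, 97% and 3.6%. GCRMA values near the low end of the scale are compressed, so a fold from or to that level depends on the background correction.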

Results

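Striatal gene expression was compared between mice with D1R-Cre deletion of TIF-IA and controls at 9 and 13 weeks of age, with 3 mice in each of the 4 groups. TIF-IA, encoded by Rrn3, is a factor RNA polymerase I needs to start transcription of ribosomal RNA genes, and D1R-Cre acts in neurons that carry the D1 dopamine receptor. The deposited log2 values of 8253 genes were analysed, and 3 arrays per group limit the precision. From Xist and Eif2s3y, 1 mouse in each control group and 1 mutant at 9 weeks were female, and all 3 mutants at 13 weeks were female. Drd1, Adora2a, Bax and Chat are not analysed here.

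Rrn3 was measured by 1 probe set, whose position relative to the deleted part is not known. Its log2 values were 8.0, 7.97 and 8.2 in the controls and 6.90, 6.96 and 6.91 in the mutants at 9 weeks. At 13 weeks they were 7.96, 7.54 and 8.04 in controls and 7.72, 7.58 and 7.18 in mutants. Rrn3 fell by 1.13 ± 0.18 (SE, n = 3) at 9 weeks, adjusted p = 0.00747, and all 3 mutants lay below all 3 controls. At 13 weeks the difference was -0.35 ± 0.18 and did not pass (adjusted p = 0.128). The change of the effect between ages was 0.78 ± 0.25, adjusted p = 0.0525, and over both ages Rrn3 fell by 0.74 ± 0.13, adjusted p = 0.000665. The change between ages passed in 4 alternative settings and the difference at 13 weeks in 1, while the fall at 9 weeks did not pass in 1.

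The comparison at 9 weeks asks which genes differ at the earlier age. Snhg1, a noncoding host gene of small nucleolar RNAs, rose from 7.51 to 10.94, a 10.8-fold difference (3.43 ± 0.25 log2, SE, n = 3 per group, adjusted p = 5.43e-05), and Snhg5, another such host, rose by 1.63 ± 0.17 (adjusted p = 0.00118). Gpx6, a glutathione peroxidase gene, fell 12.5-fold from 5.66 to 2.02 (-3.64 ± 0.20 log2, adjusted p = 6.42e-06), and 0 mutant arrays remained above the filter's percentile, so that its size depends on the low end of the scale. Genes shared by medium spiny neurons, the projection neurons of the striatum, had a median difference of -0.57, while ribosome biogenesis genes had a median of 0.31. Of 5 Snhg1 probe sets, the 3 with a mean over 6 differed by at least 3.0 log2, and the other 2, with means of 3.65 and 3.21, differed by -0.37 and 0.11. Snhg5 has 1 probe set.

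Among the other large rises at 9 weeks were the oviductal glycoprotein gene Ovgp1 (2.22 ± 0.24), the neuropeptide gene Cartpt (1.89 ± 0.26, 3.71-fold), the mitochondrial topoisomerase gene Top1mt (1.68), Epb41l4b (1.57), Mns1 (1.56), the endothelin-converting enzyme gene Ece2 (1.52) and Cyth2 (1.49). The falls included Musk (-2.62) and Cdhr1 (-2.10), whose mutant arrays were also below the percentile, the calcium release channel gene Ryr1 (-2.28), Pgam2 (-1.99), Ddit4l (-1.96 ± 0.25), Gcnt2 (-1.78), Il17rc (-1.78) and Rasl11b (-1.76 ± 0.16). Each of these passed in all 12 fits that left out 1 array, although another probe set of Ece2 differed by only 0.12. Smc5 (1.64), Nasp (1.51), Amn (1.48), Serpinb1b (-2.07), Smpd3 (-2.0) and Coch (-1.90) passed with all arrays but not in each of those fits.

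Of 21 shared medium spiny neuron genes, 5 fell at 9 weeks over all genes and 9 fell when adjusted over the list alone (list test, adjusted p = 4.22e-06, and adjusted p = 0.658 with an estimated correlation). They included the cannabinoid receptor gene Cnr1 (-1.73, with 0 mutant arrays above the percentile, so that its size depends on the low end of the scale), the actin crosslinker gene Actn2 (-1.57 ± 0.28), the potassium channel partner gene Kcnip2 (-1.04) and the retinoic acid receptor gene Rarb (-0.99). The markers of the D1 and D2 classes mostly did not pass. Tac1 differed by -0.57, Pdyn by -0.42, Drd2 by -1.03 ± 0.45 (adjusted p = 0.213), Penk by -0.58 and Ppp1r1b by -0.20. In the D1 list 1 of 6 members fell (2 adjusted over the list alone), Sfxn1 (-0.82), and in the D2 list 0 of 4 passed limma's test over all genes or adjusted over the list alone. Of 23 synapse genes, 1 fell, the glutamate receptor gene Gria1 (-1.05 ± 0.24), and 3 fell adjusted over the list alone. Their median was -0.39 (list adjusted p = 0.012, and adjusted p = 0.658 with an estimated correlation), and without mutant mouse 3 at 9 weeks the list did not pass (adjusted p = 0.181).

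Ribosome biogenesis and nucleolar genes, which build ribosomal subunits, rose as a list at 9 weeks (adjusted p = 1.26e-06, and adjusted p = 0.15 with an estimated correlation). Over all genes 4 of 49 members rose and 5 rose adjusted over the list alone. They were Nop58 (0.96), a core protein of small nucleolar ribonucleoproteins, Nol12 (0.71), Nip7 (0.67) and Ebna1bp2 (0.66), and a second probe set of Nip7 differed by -0.94, so that the mean of its probe sets differed by -0.13. Ribosomal protein genes had a median of 0.21 (list adjusted p = 0.000259, and adjusted p = 0.658 with an estimated correlation), and 2 of 40 passed, Rpsa (0.82) and Rps15 (0.61), against 3 higher and 1 lower adjusted over the list alone. Without mutant mouse 3 at 9 weeks this list did not pass (adjusted p = 0.0654).

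In the integrated stress response at 9 weeks, Ddit3 rose (1.25 ± 0.19, adjusted p = 0.0064) with Atf4 (0.75), while the chaperone gene Calr fell (-0.79). Of 23 members 2 rose and 1 fell (2 and 3 adjusted over the list alone), and the list did not pass. Among 32 autophagy genes Dram2 rose (0.75) and Ambra1 (-1.06), Ulk2 (-0.75) and Gabarapl1 (-0.65) fell, against 2 higher and 5 lower adjusted over the list alone.

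Of 22 p53 target genes at 9 weeks, Aen rose (1.16) and Sesn1 fell (-0.80), and adjusted over the list alone 1 rose and 2 fell. Cdkn1a, an inhibitor of the cell cycle, differed by -1.09 ± 0.32 and did not pass (adjusted p = 0.0741), nor did Ccng1 (0.51) or Mdm2 (0.11). The survival genes Bcl2l1 (-0.69) and Xiap (-0.59) fell and Bok (0.97) rose among 23 apoptosis genes, with 2 higher and 2 lower adjusted over the list alone, and another probe set of Bcl2l1 differed by 0.54. Microglia genes had a median of 0.30 (list adjusted p = 0.0403, and adjusted p = 0.772 with an estimated correlation) with 0 of 19 members past limma's test over all genes or adjusted over the list alone. This list did not pass without mutant mouse 3 at 9 weeks or without control mouse 3 at 9 weeks (highest adjusted p = 0.651). In mutant mouse 3 Gfap was 8.98, Aif1 was 8.11 and the mean microglia shift was 0.68. The same array had a mean shift of 0.83 in thalamic and pallidal markers (0.03 and -0.10 in the other mutants at 9 weeks) and of 0.79 in interneuron markers (-0.09 and 0.22). Slc17a6 was 7.99 (3.20 and 2.69 in the others) and Calb2 was 7.74 (2.65 and 3.11), and control mouse 1 at 13 weeks also had high values, 7.08 and 8.0, of this pair, which was singled out after its values were seen. The microglia, ribosomal protein and synapse list calls at 9 weeks, all lost without mutant mouse 3, therefore depend on that array. Its means of thalamic and pallidal markers and of interneuron markers were also high, but a broad rise of these markers is not shown. With all 3 mutants the medians of these 2 lists were 0.1 and 0.17, and 0 members passed. Over the 3 mutants, Gfap (0.92 ± 0.30) and Aif1 (0.56) did not pass, nor did Sqstm1 (0.09) or Mbp (0.02). Of 18 activated microglia genes Apoe rose (0.67), also adjusted over the list alone. Single members also passed in lists that did not. Since 5% of all genes tested passed at 9 weeks, such single calls do not set these lists apart. The glutathione transferase gene Gsta4 (1.07) of 21 antioxidant genes, Cdc20 (1.04) of 18 cell cycle genes and Ndufb10 (0.55) of 77 oxidative phosphorylation genes rose, against 2, 1 and 0 adjusted over the list alone. Rgs4 (-0.87) of 18 dopamine and cAMP signalling genes and Dnajb4 (-0.86) of 16 heat shock genes fell, against 2 and 1. The list of cell cycle and proliferation genes (median 0.28, adjusted p = 0.0569) passed in 11 alternative settings, that of cholesterol synthesis genes (-0.35, adjusted p = 0.063) in 7 and that of complement, MHC class I and interferon genes (0.11, adjusted p = 0.113) in 4.

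At 9 weeks 413 genes passed, 5% of those tested, with 167 higher and 246 lower in mutants. The split was 215 higher and 176 lower after median centring. The count was 69, 92 and 80 without control mouse 1, 2 or 3 at 9 weeks, 94, 62 and 221 without mutant mouse 1, 2 or 3 at 9 weeks, 269 and 254 without mutant mouse 1 or 2 at 13 weeks, and 1361 without control mouse 3 at 13 weeks, whose values enter through the shared spread. Of the 57 named genes that passed, 21 passed in all 12 such fits. For Actn2, Cnr1, Kcnip2, Rarb, Gria1, Nop58, Sesn1, Atf4, Aen and the other genes that lost their calls without at least 1 of the arrays at 9 weeks, the highest adjusted p lay between 0.0611 and 0.164. Amn, Coch, Rps15 and Bok did not pass after quantile normalization, Xiap not after median centring and Rgs4 after neither. Of 28 lists 6 passed, 3 up and 3 down, and another split of the same 6 mice gave 14.

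**Figure D1:**
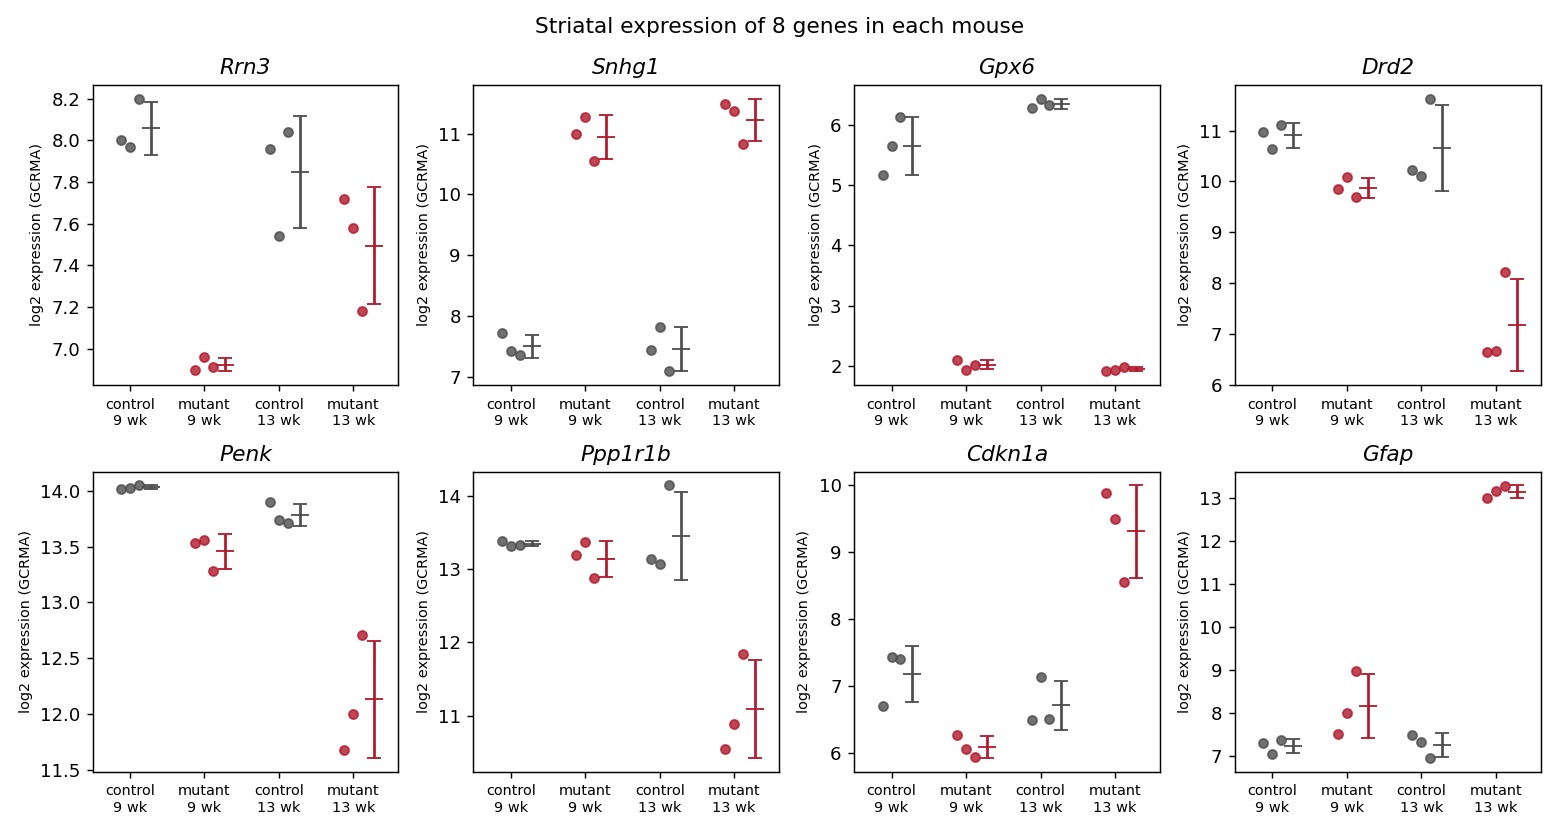
Log2 expression of 8 genes in each of the 12 mice, by genotype and age; points are mice and bars are group means ± SD (n = 3). Snhg1 and Gpx6 were already apart at 9 weeks, whereas Drd2, Penk, Ppp1r1b, Cdkn1a and Gfap passed the test at 13 weeks only.

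The comparison at 13 weeks asks which genes differ at the later age. At this age 45.4% of all genes tested passed, so a list with about that share of members past the test is not set apart by its count. All 21 measured members of the shared medium spiny neuron list fell, while reactive astrocyte, microglial and interferon genes were far higher. Gfap, the intermediate filament gene of astrocytes, rose from 7.26 to 13.15, a 59.2-fold difference (5.89 ± 0.30 log2, SE, n = 3 per group, adjusted p = 3.68e-08). Drd2, the D2 dopamine receptor gene, fell 11.2-fold from 10.66 to 7.17 (-3.48 ± 0.45, adjusted p = 7.32e-05), and Cdkn1a rose by 2.59 ± 0.32 (adjusted p = 5.92e-05).

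The shared medium spiny neuron genes had a median of -2.28 at 13 weeks, and 21 of 21 fell over all genes and adjusted over the list alone (list adjusted p = 1.57e-12, and adjusted p = 0.194 with an estimated correlation). Among them were the phosphodiesterase gene Pde10a (-3.39), Actn2 (-3.32), Kcnip2 (-2.85), Rarb (-2.28) and Ppp1r1b (-2.36 ± 0.34), which encodes DARPP-32. In the D2 list Drd2, Penk (-1.65 ± 0.22) and Upb1 (-1.67) fell, 3 of 4 members over all genes and adjusted over the list alone, and Upb1 did not pass without control mouse 2 or mutant mouse 2 at 13 weeks (highest adjusted p = 0.109). In the D1 list Tac1 (-1.56 ± 0.20), Sfxn1 (-1.42) and Isl1 (-0.99) fell, 3 of 6 members by either adjustment, and Pdyn (-0.72, adjusted p = 0.0802) did not pass. Of 11 interneuron genes 1 rose, the choline transporter gene Slc5a7 (1.33), and 0 adjusted over the list alone. Slc5a7 was not called without any 1 of the 3 mutants at 13 weeks, control mouse 2 or 3 at 13 weeks, or control mouse 2 at 9 weeks (highest adjusted p = 0.143), nor after quantile normalization.

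Of 23 synapse genes 19 fell at 13 weeks (20 adjusted over the list alone), with a median of -1.36 (list adjusted p = 3e-07, and adjusted p = 0.2 with an estimated correlation). They included the GABA receptor gene Gabrd (-3.19), the vesicle protein gene Rab3a (-2.34), Gria1 (-1.98) and Gria2 (-1.88). Dopamine and cAMP signalling genes had a median of -1.58 (list adjusted p = 0.000199, and adjusted p = 0.216 with an estimated correlation), with 12 of 18 lower, and 12 lower and 1 higher adjusted over the list alone. Rasgrp2 (-4.13), Gnb5 (-2.17) and Rgs4 (-1.77) were among them. Large falls were those of Cd4 (-5.22 ± 0.32, 37.3-fold, adjusted p = 1.65e-07), Gpx6 (-4.40, 21.2-fold), Icam5 (-4.17), Smpd3 (-4.12), the adrenergic receptor gene Adra2c (-4.00), Ido1 (-3.84), Wnt2 (-3.77), the calmodulin-binding gene Nrgn (-3.62), Coch (-3.57), the muscarinic receptor gene Chrm1 (-3.53) and Cplx2 (-3.53). For Cd4, Gpx6, Adra2c and Wnt2, 0 mutant arrays lay above the percentile, so that the sizes of their falls depend on the low end of the scale.

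Reactive astrocyte genes rose at 13 weeks in 14 of 14 members over all genes and adjusted over the list alone, with a median of 5.63 (list adjusted p = 6.87e-14, and adjusted p = 0.0866 with an estimated correlation). Serpina3n rose from 5.0 to 13.03, 261-fold (8.03 ± 0.49), and Lcn2 (7.01), Osmr (6.54), Cd44 (6.4), Timp1 (5.90) and Emp1 (5.38) rose with it, each with 0 control arrays above the percentile. Of 19 astrocyte markers 14 rose (15 adjusted over the list alone), with a median of 1.48 (list adjusted p = 8.89e-06, and adjusted p = 0.0866 with an estimated correlation). The water channel gene Aqp4 (2.85) and the glutamate transporter gene Slc1a3 (1.51) were among them.

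Activated microglia genes rose in 17 of 18 members at 13 weeks (18 adjusted over the list alone), with a median of 4.02 (list adjusted p = 7.45e-14, and adjusted p = 0.0866 with an estimated correlation). Cst7, which encodes a cystatin, rose from 2.21 to 10.50 (8.29 ± 0.30, adjusted p = 1.95e-09), a 313-fold difference with 0 control arrays above the percentile, so that its size depends on the low end of the scale. Clec7a (7.81), Lgals3 (5.80) and Ccl6 (5.67) rose as well. Of 19 general microglia markers 17 rose (19 adjusted over the list alone), with a median of 2.60 (list adjusted p = 4.73e-11, and adjusted p = 0.194 with an estimated correlation), including Ly86 (3.94), Mpeg1 (3.85), Aif1 (2.91), Ctss (2.60) and Fcgr3 (2.51). Complement, MHC class I and interferon genes rose in 24 of 24 members over all genes and adjusted over the list alone, with a median of 4.31 (list adjusted p = 2.46e-20, and adjusted p = 0.0901 with an estimated correlation). Ifit1 (6.96), Usp18 (6.81), Gbp3 (5.44) and Rsad2 (5.08) were among them, and the interferon-induced genes Oasl2 (7.76), Cxcl10 (7.17), Bst2 (6.79) and Rtp4 (6.58) and the protease inhibitor gene A2m (7.99) were among the largest rises of all. As for Cst7, 0 control arrays lay above the percentile for Clec7a, Lgals3, Ifit1, Usp18, Rsad2, Oasl2, Rtp4 and A2m.

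Markers of other cell types moved unevenly at 13 weeks. Of 14 oligodendrocyte genes 2 rose over all genes and adjusted over the list alone, with a median of 0.33 (list adjusted p = 0.198), and Mbp differed by 0.07, or by -0.32 (adjusted p = 0.024) as the mean of its probe sets. All 4 precursor markers measured rose by either adjustment, among them Vcan (2.83), and 9 of 12 endothelial and mural genes rose (10 adjusted over the list alone), with a median of 1.12 (list adjusted p = 0.00313, and adjusted p = 0.325 with an estimated correlation), including Vwf (2.27). The choroid plexus gene Ttr rose by 2.26 ± 0.77 but was uneven, at 5.26, 3.35 and 7.32 in the 3 mutants, with 0 control arrays above the percentile. It did not pass without mutant mouse 1 or 3 or any 1 of the controls at 13 weeks (highest adjusted p = 0.107), and 2 of 3 members of its list rose, or 3 adjusted over the list alone. Of 4 cortical markers Rorb rose (2.32), also adjusted over the list alone, and of 7 thalamic and pallidal markers 1 rose and 2 fell by either adjustment. The single blood marker Hbb-b2 differed by -0.13.

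Of 22 p53 target genes 13 rose at 13 weeks, and adjusted over the list alone 13 rose and 1 fell (median 1.23, list adjusted p = 0.00372, and adjusted p = 0.38 with an estimated correlation). Pmaip1 (3.40), Fas (2.85), Aen (2.25), Ccng1 (2.14) and Cdkn1a rose, and Mdm2 rose by 0.74 ± 0.22 but not without mutant mouse 1 at 13 weeks (adjusted p = 0.0818). Cell cycle genes rose in 12 of 18 members and fell in 1 (13 and 1 adjusted over the list alone), with a median of 1.56 (list adjusted p = 0.000953, and adjusted p = 0.194 with an estimated correlation), including Ccnd1 (3.43), Mcm3 (2.88), Birc5 (2.20) and Top2a (2.19). Apoptosis genes rose in 10 of 23 members and fell in 3 by either adjustment (median 0.47, list adjusted p = 0.0266, and adjusted p = 0.251 with an estimated correlation), including Casp8 (3.13), the death receptor gene Tnfrsf1a (3.13) and Casp1 (2.39). This list did not pass without control mouse 3 at 13 weeks (adjusted p = 0.0772). For Pmaip1, Mcm3, Birc5, Casp8 and Casp1, 0 control arrays lay above the percentile, so that the sizes of their rises depend on the low end of the scale.

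Heat shock genes rose in 7 of 16 members at 13 weeks by either adjustment (median 0.36, list adjusted p = 0.0416, and adjusted p = 0.38 with an estimated correlation), including Hspb1 (3.49), Hspb8 (2.32) and Cryab (1.39), and the list did not pass without control mouse 3 or mutant mouse 1 at 13 weeks (highest adjusted p = 0.13). In the stress response list Atf3 (5.10) and Atf4 (1.66) were among 8 rises and 1 fall of 23, also adjusted over the list alone (list adjusted p = 0.0909). Hmox1 (4.43) and Mt2 (2.01) were among 8 rises and 4 falls of 21 antioxidant genes, 9 and 4 adjusted over the list alone (list adjusted p = 0.174). For Atf3 and Hmox1, too, 0 control arrays lay above the percentile. Oxidative phosphorylation genes had 13 falls and 2 rises of 77 (5 and 2 adjusted over the list alone), with a median of -0.15 (list adjusted p = 0.0416, and adjusted p = 0.613 with an estimated correlation). This list did not pass after quantile normalization (adjusted p = 0.113), with sex as a term (adjusted p = 0.28), or without control mouse 2, mutant mouse 1 or mutant mouse 2 at 13 weeks (highest adjusted p = 0.232).

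The lists tied to ribosome supply did not pass at 13 weeks. Ribosome biogenesis genes had 13 rises and 1 fall of 49 by either adjustment and a median of 0.20 (list adjusted p = 0.0909), ribosomal protein genes had 1 rise and 2 falls of 40 (1 and 1 adjusted over the list alone, list adjusted p = 0.865), and the RNA polymerase I machinery had 1 rise and 2 falls of 14 by either adjustment (list adjusted p = 0.558). Autophagy and lysosome genes had 6 rises and 10 falls of 32 (6 and 11 adjusted over the list alone), with Lamp2 (2.77) and Lamp1 (1.10) higher and Sqstm1 (-0.13) not past the test. Of 15 axon injury genes 8 rose and 2 fell (8 and 4 adjusted over the list alone, list adjusted p = 0.0774). Of 16 cholesterol synthesis genes 4 fell (3 adjusted over the list alone), and of 13 immediate early genes 3 rose (1 adjusted over the list alone), among them Jun (2.97) and Fos (2.92), the latter uncalled without control mouse 2 at 9 weeks, control mouse 3 at 13 weeks or any 1 of the mutants at 13 weeks (highest adjusted p = 0.15).

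At 13 weeks 3744 genes passed, 45.4% of those tested, with 1933 higher and 1811 lower. Differences of at least 4-fold numbered 479 rises and 225 falls, and for 151 of these rises 0 control arrays, and for 19 of these falls 0 mutant arrays, lay above the percentile. All 3 mutants were female against 1 of 3 controls, and the medians against the female and against the male controls were -2.53 and -2.02 for shared medium spiny neuron genes, 5.61 and 5.57 for reactive astrocyte genes, 2.61 and 2.72 for microglia markers, 4.34 and 4.22 for complement, MHC class I and interferon genes and 0.1 and 0.33 for oligodendrocyte markers. Of 28 lists 15 passed, 10 up and 5 down.

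**Figure D2:**
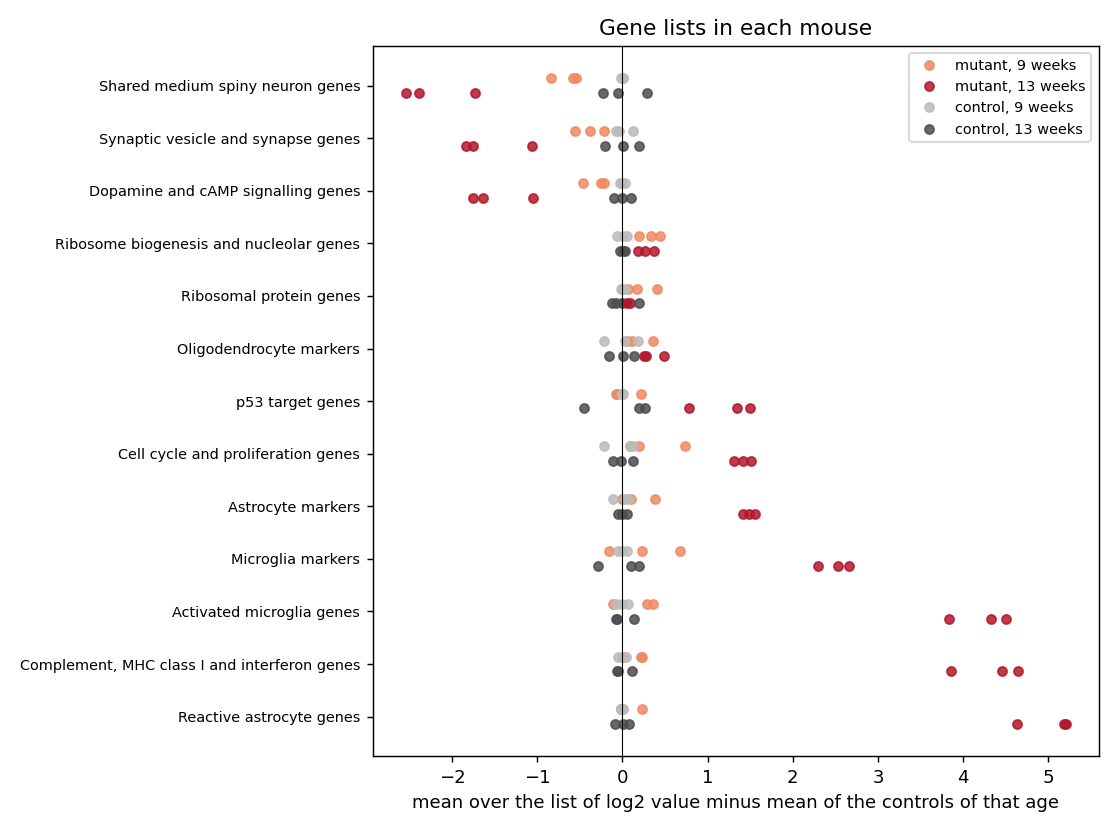
Mean over each of 13 gene lists of the log2 value minus the mean of the controls of the same age, in each of the 12 mice; points are mice. At 13 weeks the reactive astrocyte, activated microglia and interferon lists are highest (median differences 5.63, 4.02 and 4.31) and the shared medium spiny neuron list is lowest (-2.28).

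The difference of the genotype effect between ages was tested gene by gene. It was positive for the reactive and interferon genes, led by Cst7 (8.28), A2m (7.74), Oasl2 (7.68), Serpina3n (7.66), Clec7a (7.36) and Cxcl10 (7.06), with Gfap at 4.97 and Aif1 at 2.35. The limit set by the low end of the scale at 13 weeks holds here too for Cst7, A2m, Oasl2, Clec7a, Cd4 and Adra2c. Large negative changes were those of Cd4 (-3.98), Rasgrp2 (-3.65), Dmkn (-3.31), Chrm1 (-3.24), the postsynaptic scaffold gene Dlg4 (-3.20), Pde10a (-3.09), Adra2c (-3.01), Cplx2 (-2.95) and Gabrd (-2.82), of which Cplx2 lost its call in 8 of the 12 fits without 1 array (highest adjusted p = 0.0891). Cdkn1a had an effect of -1.09 at 9 weeks and 2.59 at 13 weeks, a change of 3.69 ± 0.46 (SE, n = 3 per group, adjusted p = 0.000152), and Ccng1 changed by 1.63. Among medium spiny neuron markers Ppp1r1b (-2.16, adjusted p = 0.00854) and Drd2 (-2.45, adjusted p = 0.0188) passed, as did Tac1 (-0.99, adjusted p = 0.027) and Penk (-1.08, adjusted p = 0.0324). Drd2 did not pass without mutant mouse 1 or 2 at 13 weeks (highest adjusted p = 0.0547). Tac1 and Penk each lost the call in 8 of the 12 fits without 1 array (highest adjusted p = 0.0751 and 0.0846). In all, 1522 genes passed, 996 with a higher and 526 with a lower effect at 13 weeks, and 16 of 28 lists passed, 12 up and 4 down. With an estimated correlation 1 list passed, that of reactive astrocyte genes (adjusted p = 0.0379). Ribosomal protein genes (median -0.17, adjusted p = 0.0558) passed in 8 alternative settings.

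Over both ages 3662 genes passed, 1845 higher and 1817 lower. The rises were led by Serpina3n (4.20) and Cst7 (4.15), with Snhg1 at 3.6 and Gfap at 3.40, and the falls included Gpx6 (-4.02), Cd4 (-3.23), Smpd3 (-3.06), Icam5 (-2.83), Coch (-2.74), Wnt2 (-2.55), Actn2 (-2.45) and Ryr1 (-2.41). Of these, Cst7 in controls and Gpx6 in mutants had 0 arrays above the percentile at both ages, and Cd4, Wnt2 and Ryr1 had 0 in mutants at 13 weeks. Snhg1, Snhg5, Gpx6, Actn2, Rarb and Kcnip2 were among genes past the test at each age. Of genes called at 9 weeks, 94 were higher and 185 lower at both ages, where independent lists would share 39.1 and 54. The calls at the 2 ages are not fully independent, because both tests use the same spread of a gene. Another 2 and 5 genes were called in opposite directions, and 127 were not called at 13 weeks. Rasl11b, Cartpt, Top1mt, Epb41l4b and Mns1 were among 40 genes called at 9 weeks only whose effect had changed in the opposite direction by the interaction test. The interaction contains the same difference at 9 weeks by which these genes were picked. It is therefore no independent evidence that their effects faded. Across genes, which are not independent replicates, the effects at the 2 ages correlated at r = 0.462 (rho = 0.508).

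**Figure D3:**
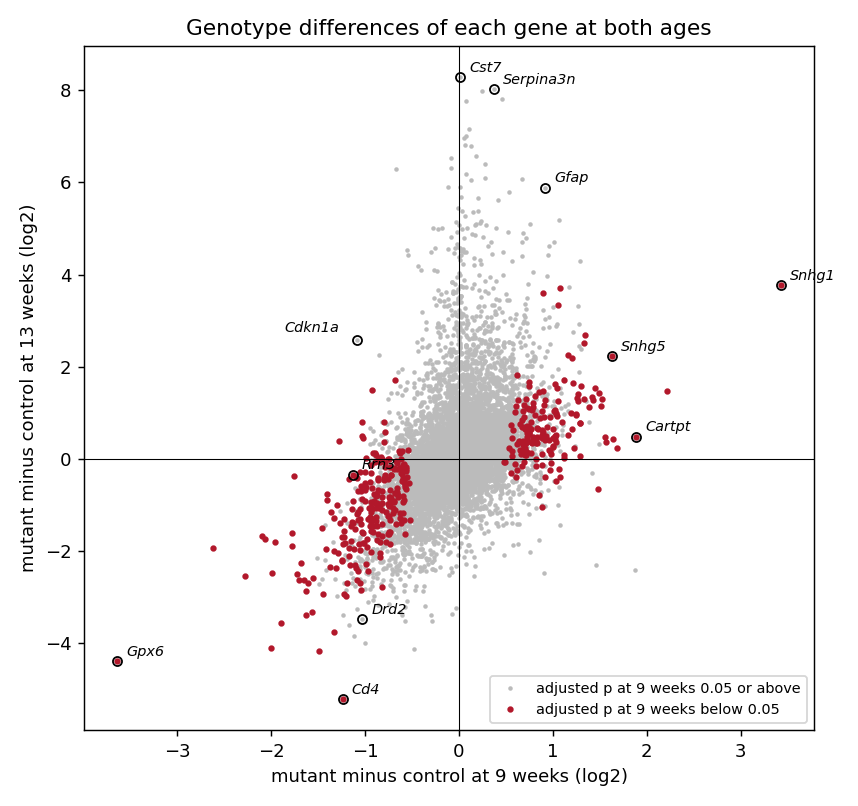
Log2 difference, mutant minus control, at 9 weeks (horizontal) and 13 weeks (vertical) for each of 8253 genes; each point is a gene and red points passed the test at 9 weeks. Snhg1 (3.43 and 3.77) and Gpx6 (-3.64 and -4.40) lie far out at both ages, and the largest rise at 13 weeks, Cst7 (8.29), lies near 0 at 9 weeks (0.01).

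Age in controls asks what changes between 9 and 13 weeks without the mutation. The actin regulator gene Cap1 rose by 2.97 ± 0.39 (SE, n = 3 per group, adjusted p = 0.0255) from a level at which 0 control arrays at 9 weeks lay above the percentile, so that its size depends on the low end of the scale, and Otub1 (2.27), the splicing regulator gene Rbfox2 (1.84), the profilin gene Pfn1 (1.69) and the motor gene Kif5c (1.51) rose too. Tmem268 (-1.06), Car15 (-0.98), Plekha6 (-0.96), Usp48 (-0.87) and Lrrk2 (-0.78) fell, Car15 to a level with 0 control arrays above the percentile at 13 weeks. In all 12 genes passed, 7 higher and 5 lower, against 10 and 1 after median centring and 8 and 3 after quantile normalization, and Tmem268, Lrrk2, Car15 and Usp48 did not pass after median centring, nor the first pair after quantile normalization. Of these 10 genes 0 passed in every fit without 1 array. Microglia markers (median 0.22, adjusted p = 0.0125, and adjusted p = 0.996 with an estimated correlation) and ribosomal protein genes (0.17, adjusted p = 2.31e-06, and adjusted p = 0.832 with an estimated correlation) passed as lists, but not without control mouse 2 at 13 weeks (adjusted p = 0.212 and 0.066). Control mouse 3 at 13 weeks correlated with its group at 0.936 and 0.945, where the other pair reached 0.991, and without it 25 genes passed. The count was 0 in limma's test without any 1 of the controls at 9 weeks (936, 1136 and 914 genes at an unadjusted p under 0.05), without mutant mouse 2 at 9 weeks (1247), and without control mouse 1 (1914) or mutant mouse 1 (1274) or 2 (1256) at 13 weeks. It was 6 and 20 without mutant mouse 1 or 3 at 9 weeks, 3 without control mouse 2 and 7 without mutant mouse 3 at 13 weeks. In mutants 2700 genes changed with age, 1330 up and 1370 down, among them Cst7 (8.30), Serpina3n (8.25), A2m (7.94) and Ifit1 (6.94), where Cst7 and Ifit1 had 0 mutant arrays above the percentile at 9 weeks.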

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

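The comparison of microglia with oligodendrocyte markers and the term for sex were chosen only after the result was seen, as was the use of the planned fit without control mouse 3 to weigh that array. The other tests of this part were planned.

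The genotype effect differed between 9 and 13 weeks by a test of the difference itself. It differed for 1522 genes and for 16 gene lists. The medians of the change in effect were 5.16 for reactive astrocyte genes, 4.07 for complement, MHC class I and interferon genes, 3.57 for activated microglia genes, 2.27 for microglia markers, 1.29 for astrocyte markers and 1.28 for endothelial and mural markers. They were -1.51 for shared medium spiny neuron genes, -1.16 for dopamine and cAMP signalling genes and -0.98 for synapse genes. Smaller changes were 1.02 for p53 targets, 0.90 for cell cycle genes, 0.48 for apoptosis, for stress response and for axon injury genes, 0.46 for heat shock genes and -0.20 for oxidative phosphorylation genes. With an estimated correlation only the reactive astrocyte list passed (adjusted p = 0.0379). The oxidative phosphorylation list did not pass without control mouse 2 or mutant mouse 1 at 13 weeks or mutant mouse 3 at 9 weeks (highest adjusted p = 0.227), nor the axon injury list without control mouse 2 at 13 weeks (adjusted p = 0.0789).

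The splits of the arrays bear on chance. For the interaction, 4 of 100 splits drawn from 200, the real one included, gave as many genes (real 1522, highest other 2020) and 4 as many lists (real 16, highest other 16). These splits exchange the ages within each genotype, so they also break the change with age in mutants (2700 genes). The 3 other splits as large all kept the mutants of 1 age together and so followed a structure of the samples. For the interaction itself, the splits therefore cannot exclude chance. For both ages 1 of 100 splits, the real one, gave as many genes (real 3662, highest other 2269). That share is under 0.05, so a chance split of the arrays is argued against. It is not excluded, since not all possible splits were drawn and the structure of the larger ones was not checked.

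With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. The real split alone gave its count of genes at 9 weeks (413, highest other 0), at 13 weeks (3744, highest other 1), for age in controls (12, highest other 0) and for age in mutants (2700, highest other 0), which is 1 split in each case. For lists at 13 weeks it was again 1 split (15, highest other 13). At 9 weeks 7 of the 10 splits gave as many lists (real 6, highest other 14), and for age in controls 5 did (real 2, highest other 7). In the splits with 0 genes the tool was limma.

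The rise of glial and immune genes beside the fall of medium spiny neuron genes at 13 weeks may reflect several things. A lower share of neurons alone would raise every other cell type alike, whereas microglia markers rose beyond oligodendrocyte markers by at least 1.81 log2 in each of the 3 mutants, against a larger SD of 0.33 within a group. The tables therefore argue against it as the whole cause. Sex was unequal between the groups. A sex difference alike in all groups is argued against as the whole cause, because 89.7% of the calls remained with the same sign with sex as a term. All 3 mutants at 13 weeks were female, so that term rests on the other groups. An effect of the mutation that differs between the sexes at 13 weeks could not be tested. Control mouse 3, which stood apart, is argued against as the whole cause because 90% of the calls remained without it. A loss of neurons together with more or activated glia, and a change of expression within cells, stay open, and the design does not separate them.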

How the results depend on the processing

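The fits with a term for sex, with female or male arrays only and without genes on X and Y were chosen after seeing the data; the other alternatives were planned. Quantile normalization, a trended and robust prior, the mean of probe sets and a least change of 1.5-fold kept every count of genes within 1.5 times, as did median centring, sex as a term and the removal of genes on X and Y. Results for named genes kept their side of the threshold in 470 cases after quantile normalization, with 9 lost and 4 gained, and in 466 after median centring, with 8 lost and 9 gained. The unmoderated test and the fit to the compared groups were not run for the interaction or both ages, nor median centring for lists. Unless stated, the cause was not tested.

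Leaving out 1 array gave 62 to 1361 genes at 9 weeks, 2901 to 3951 at 13 weeks, 1070 to 1950 for the interaction, 3050 to 4240 for both ages, 0 to 25 for age in controls and 1899 to 3834 for age in mutants. Lists numbered 4 to 9, 12 to 15, 14 to 17 and 0 to 2 (9 weeks, 13 weeks, interaction, age in controls), and r lay between 0.417 and 0.47. The highest count of genes in each comparison came without control mouse 3 at 13 weeks, which adds to the shared spread.

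At 9 weeks the gene count was 1053 in a fit to the compared groups only, which leaves out that spread, and 827 at an adjusted p under 0.1. Array weights gave 3832 there, 4302 for the interaction, 5701 for both ages, 1926 for age in controls and 5752 for age in mutants, but the weights did not converge (0.0587 to 23.7). The unmoderated test called 1939 genes at 13 weeks. For age in controls the count was 59 with no filter, 7 with the 60th percentile filter, 25 with every probe set, 51 at an adjusted p under 0.1, 0 in the compared groups only by limma (950 genes at an unadjusted p under 0.05) and 0 by the unmoderated test (905).

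Camera with an estimated correlation called 0 lists at 9 weeks (3 at an unadjusted p under 0.05), 0 at 13 weeks (6), 1 for the interaction and 0 for age in controls (0), against 3 at 9 weeks and 1 for age in controls by fry, which does not compare a list with other genes. A fit to the compared groups only called 10 lists at 9 weeks.

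Female arrays only, with 1 control at each age and 1 mutant at 9 weeks that are assumed to vary like the rest, gave 2 genes at 9 weeks, 1701 genes and 0 lists (5 at an unadjusted p under 0.05) for age in controls, where control mouse 3 is the only one at 13 weeks. Male arrays only gave 197 genes and 14 lists at 9 weeks, and for age in controls 0 genes by limma (1212 at an unadjusted p under 0.05) and 4 lists.

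Results that reversed were Nip7 at 9 weeks (-0.13), Taf1d (0.14) and Mbp (-0.32) at 13 weeks with the mean of probe sets, since their probe sets disagree, and the microglia list at 9 weeks with female arrays only (-0.04, 1 mouse of each genotype).

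The replicate number as a block gave 3 genes for age in controls and moved no other count by over 1.5 times. Of 18 pairs of same-numbered arrays 4 correlated above 0.1 (-0.12 to 0.316), but 9 of 12 arrays correlated best with their own number. Whether the numbers mark a shared litter, day or batch is not known and could not be decided from these correlations. Values near the low end limit folds of genes unseen in 1 group.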

Other observations

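The tests of Snhg1 probe sets, of protein-coding host genes and of the control mouse apart were chosen only after the results were seen. The prediction for the decay factors was recorded as written beforehand, but the rise it addresses was found in these data.

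Snhg1 and Snhg5 rose at both ages, Snhg1 by 3.43 and 3.77 and Snhg5 by 1.63 and 2.23 log2. Binding of another transcript by a Snhg1 probe set is argued against by the smallest difference, 3.0, over the 3 probe sets with a mean over 6, although all may share sequence. A raised output of protein-coding host genes of small nucleolar RNAs is argued against, since the higher of the medians of the 18 measured was 0.13. Of 6 measured noncoding hosts, 2 were higher at 9 weeks, and 4 were higher and 1 was lower at 13 weeks (medians 0.48 and 0.97). Beyond Snhg1 and Snhg5, Gas5 (0.87, adjusted p = 0.0233) and Snhg6 (1.08, adjusted p = 0.00953) rose and Snhg11 (-1.19) fell at 13 weeks, so a rise of noncoding hosts as a class stays open. Reduced nonsense-mediated decay would raise its self-regulated factors. Of 7 such factors 3 were measured, Upf1, Upf2 and Smg5, with medians of -0.35 at 9 weeks and -0.46 at 13 weeks. These showed no rise, with 0 called higher at either age. They are few, each median is the value of 1 gene, and they come from whole striatum. Decay in the D1 neurons therefore could not be decided. An effect of TIF-IA loss on noncoding host transcripts in particular remains a hypothesis that was not tested.

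Control mouse 3 at 13 weeks differed by more than 1 log2 from the mean of the other 2 controls in 1701 genes (20.6%). Its sex is argued against by a correlation of only 0.07 between the female-minus-male differences of the controls at the 2 ages, and RNA degradation by its actin 3-prime minus 5-prime value of 0.82, lower than in the other arrays (1.05 to 1.96). Tissue from a neighbouring region could not be decided, as the highest median deviation of the neighbouring-region lists, 0.21, came from lists with few measured members. GC content was not tested, because probe sequences were not at hand, and no biological explanation other than sex was tested.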
